A study of Escherichia coli str. K-12 substr. MG1655 with 3 samples.

How the data were processed

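Total RNA of 3 samples of Escherichia coli K-12 MG1655 was sequenced as paired-end reads of 150 bases. Per the labels' protocols, cells were grown at 37 °C, 4.5 mL of culture was drawn for each library, and RNA was extracted with the RNAsnap method (hot formamide). The LB library was made by Azenta with TURBO DNase, the QIAGEN FastSelect kit for rRNA depletion and an NEBNext Ultra II library kit, on an Illumina instrument. The glucose and xylose phase libraries were made by a Harvard core facility with Ribo-Erase depletion and a KAPA HyperPrep kit on an Illumina NextSeq500. Diauxic growth was started at an OD600 of 0.004 from cells grown overnight in 0.2% glucose, and whether both diauxic samples came from 1 flask is not given in the sources used here. Medium is therefore confounded with provider, depletion kit, library kit, instrument and culture density in any comparison with LB, and carbon source with culture density between the phases.

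The deposited files hold, per the file headers, the output of the quantifier Salmon, and the submitters' processing notes name version 1.8.0. The expected counts are the reads that the authors' Salmon run assigned to each feature, not normalized and not always whole. The deposited TPM values are those counts divided by effective length and scaled to the same total over all features of a library. The files also give the length and the effective length of each feature in bases, as deposited. The genome build, read trimming, strand setting and Salmon options are not given in the sources used here. Reads of a unit and of an overlapping or antisense transcript can therefore not be told apart, and reads shared by near-identical copies were divided by Salmon's model.

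The features are transcription units rather than single genes. All 3 files share 2614 units, of which 1890 hold 1 gene and 724 hold several, up to 15. The LB file also lists 92 ERCC spike-in sequences. All 3935 gene names matched the gene table of assembly ASM584v2, 3920 by current symbol and 15 by an older symbol. That table was used only for names, gene types and the gene positions from which overlaps between units were found. Of the 2614 units, 2446 hold a protein-coding gene and 168 hold none. The design fixed before the data were examined spoke of genes, and its rules were applied to units, so a unit counts once however many genes it holds. No ribosomal RNA unit was listed, so no share of ribosomal RNA is given.

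Expected counts were rounded to whole numbers. Units with a protein-coding gene and at least 10 reads in 1 library were kept (2387 units). Scaling factors were computed with the TMM method of edgeR 4.0.16 in R 4.3.3 over the 3 libraries, and were 0.972 for LB, 1.00 for the glucose phase and 1.02 for the xylose phase. For the log2 ratio of 2 libraries, 0.5 was added to each count before scaling, so the ratio of a unit near 0 reads depends on the depths of the libraries. A unit was counted as higher or lower when its log2 ratio was at least 2 in size and the higher library had at least 50 reads. This is a rule of size, not a test. Intervals of ratios were exact conditional binomial intervals at 95%, and intervals of shares were exact Clopper-Pearson intervals. Reads are not independent molecules, since no molecular identifiers were used. Where a library had 0 reads, the ratio was computed against 3 reads in that library and is given as a lower bound. This floor is less strict than the exact 95% interval, whose lower end is 50.0 in place of 62.2 for insE1-insF1 and 8110 in place of 9976 for rpmJ in LB against the glucose phase. That limit of 3 reads corresponds to 0.0899 scaled CPM in LB, 0.521 in the glucose phase and 0.623 in the xylose phase.

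Depth differed between the libraries. Reads on protein-coding units totalled 34317059 in LB, 5738786 in the glucose phase and 4702294 in the xylose phase, and the median tested unit had 1210, 239 and 209 reads. The 10 coding units with the most reads took 34.8% of all assigned reads in LB, 23.5% in the glucose phase and 23.8% in the xylose phase. Units without a protein-coding gene took 5.56%, 8.27% and 8.28%, and stayed outside the scaling and the counts.

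Before the data were examined, 58 gene lists of pathways, regulons and complexes were fixed, and 56 had measured units (608 of 709 listed genes). The lists of ribosomal RNAs and of small RNAs had no tested unit. Each unit was counted once per list, and 11 units belonged to more than 1 list. A list's median log2 ratio was placed among 10000 random lists of the same number of units, drawn from the same 10 bins of mean expression. Units named in the text were chosen by a rule fixed before the data were examined. For the xylose phase against the glucose phase and for LB against the glucose phase, it took the 8 largest ratios in each direction among the counted units. It also took the 2 units that moved most in each list outside the 2.5th to 97.5th percentiles, any counted unit that moved most against its list, and 11 units fixed by name, those of xylA, xylF, ptsG, crp, lacZ, malE, acs, gapA, metE, rpsA and fliC. For LB against the xylose phase it took the 3 largest ratios in each direction, and for levels the 5 features with the highest TPM in each library. This gave 55, 71 and 6 named units. Units outside this rule are named only in the closing parts, except argI as the near copy of argF, and cyoE-cyoD-cyoC-cyoB-cyoA, the srl unit, eno-pyrG, purA and purC, which went against their lists and were chosen after their values were seen.

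Alternatives fixed beforehand were DESeq2 1.42.0 size factors, total counts of the tested units or of all features, deposited TPM plus 1 or plus 0.1, counts divided by each library's effective length, a prior count of 5, minimums of 10 and 200 reads, no filter on units, and thinning to the smallest library. Alternatives added after seeing the data were units of at least 150 or 300 bases, leaving out insertion sequence units, and leaving out units inside other units. A planned check for a trend with distance from the replication origin was not run, since the sources used here name no genome build. Gene positions of ASM584v2 were used for overlaps of units only, so a trend of the ratio with position stays unchecked. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

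The counting rule was tested on simulated data drawn from the real units' means and depths over 2387 units, with 50 units changed at each fold. Changed units came only from those with at least 50 expected reads in the library compared against. The shares given here therefore do not cover units with fewer reads. For the xylose phase against the glucose phase, it counted 0% of units changed 2-fold, 58% of those changed 4-fold and 100% of those changed 8-fold and 16-fold. For LB against the glucose phase the shares were 0%, 48%, 100% and 100%, and for LB against the xylose phase 0%, 50%, 100% and 98%. None of 2187 unchanged units was counted in any of the 3 comparisons, but the simulation held counting noise only, so it says nothing about variation between cultures or libraries.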

Results

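Messenger RNA levels were measured by RNA sequencing in the Escherichia coli K-12 strain MG1655, a wild-type laboratory strain, in 3 samples. The first grew in LB, a rich medium of peptides and yeast extract, to a density of 0.33 (OD600, the optical density of the culture). The other 2 libraries came from growth in a minimal medium holding 0.025% glucose and 0.025% xylose, which the cells use in sequence (diauxic growth). They were sampled at an OD600 of 0.18, while glucose was being used (glucose phase), and at 0.47, while xylose was being used (xylose phase). Each group had 1 library, so no difference has a replicate check, no test between conditions was made and no p-value is given. Reads assigned to the listed features totalled 36348145 in LB, 6256200 in the glucose phase and 5127035 in the xylose phase. Unassigned reads are not given in the sources used here, so shares of reads are shares of assigned reads. The measured features were transcription units, named by their genes joined with hyphens, and 2387 units with a protein-coding gene entered the comparisons. The 95% intervals of ratios and shares are exact, and they and the limits from 0 reads cover counting error only.

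To set the level of each transcript within a library, as a bulk reference for levels measured by imaging (not analysed here), the deposited TPM values (reads divided by effective length and scaled to the same total in each library) were ranked. In all 3 libraries the highest level was that of ssrA, the RNA that rescues stalled ribosomes, at 150855 TPM in LB, 204366 in the glucose phase and 233319 in the xylose phase. It took 3.79% of all assigned reads in LB (95% interval 3.78 to 3.79), 5.75% in the glucose phase (5.73 to 5.76) and 6.19% in the xylose phase (6.17 to 6.21). The gene lpp, which encodes the major outer membrane lipoprotein, ranked among the highest 5 in each library, at 128217 TPM in LB, 40490 in the glucose phase and 39690 in the xylose phase. The other features among the highest 5 in LB were cspE, a member of the cold shock protein family, at 32529 TPM, rpmH, a ribosomal protein gene, at 31597 and gcvB, a small RNA, at 26368. In the glucose phase they were rnpB, the RNA of RNase P, at 66912 TPM and the transfer RNA genes glyT at 42637 and gltU at 32378. In the xylose phase they were rnpB at 55979 TPM, the ribosomal protein gene rpmJ at 24406 and the transfer RNA gene thrU at 22973. TPM is divided by effective length, and this was 4.75 bases for rpmH in LB, 1.05 bases for glyT in the glucose phase and 1.07 bases for thrU in the xylose phase, so TPM values of such short features rest on very small divisors. In the xylose phase the deposited effective length of glyT was its full 75 bases, which gave 419 TPM from 255 reads. The glucose phase had 469 reads of glyT, and in scaled counts glyT was only 1.54-fold lower in the xylose phase. Its ranks in the 2 phases are therefore not comparable. For lpp the effective length was 48.5 bases in LB, 81.4 in the glucose phase and 82.0 in the xylose phase. Part of its higher TPM in LB therefore comes from the smaller divisor.

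Levels of the protein-coding units spanned nearly 3 orders of magnitude in each library. The 5th to 95th percentiles of TPM over the tested units ran from 1.10 to 623 in LB, from 0.796 to 783 in the glucose phase and from 1.03 to 879 in the xylose phase. Of the 2446 units with a protein-coding gene, 2368 had at least 10 reads in LB, 2199 in the glucose phase and 2191 in the xylose phase. After LB and the glucose phase were thinned to the depth of the smallest library, these counts were 2163 in LB and 2158 in the glucose phase. Across the 2387 tested units, which are not independent replicates, log2(TPM + 1) of the xylose and glucose phases had a Pearson r of 0.966 and a Spearman rho of 0.968. For LB and the glucose phase r was 0.820 and rho 0.824, and for LB and the xylose phase r was 0.796 and rho 0.801.

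The comparison of the xylose phase with the glucose phase asked which transcripts differed between the 2 stages of diauxic growth. The genes of xylose use were far higher in the xylose phase. The unit xylB-xylA, encoding xylulokinase and xylose isomerase, was 752-fold higher (95% interval 653 to 876), from 186 reads in the glucose phase to 117320 in the xylose phase. The xylose-proton symporter gene xylE was 443-fold higher (299 to 724), and xylF-xylG-xylH-xylR, which holds the xylose ABC transporter genes and the gene of the activator XylR, was 267-fold higher (233 to 311). The gene ptsG, encoding the glucose transporter of the phosphotransferase system, was 10.6-fold lower (10.0 to 11.3). The list medians of iron acquisition, nitrogen limitation and arginine synthesis were also lower in the xylose phase. In these lists 4 of 13, 2 of 3 and 0 of 8 units were at least 4-fold lower.

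**Figure D1:**
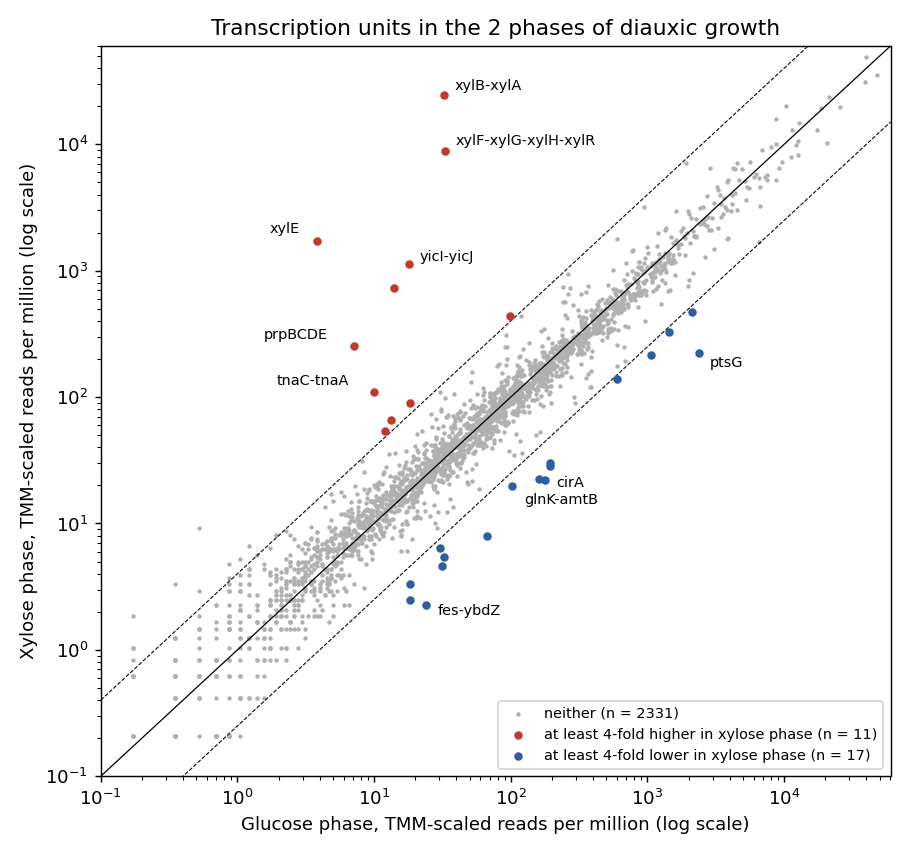
Levels of 2359 protein-coding transcription units in the glucose phase (x axis) and the xylose phase (y axis), 1 library each, in TMM-scaled CPM on log scales. The solid line marks equal levels and the dashed lines mark a 4-fold difference, and the coloured points are the 11 units at least 4-fold higher and the 17 at least 4-fold lower in the xylose phase with at least 50 reads in the higher library, with the xyl units farthest above the line, while 28 units with 0 reads in 1 or both libraries are not drawn.

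Over all 2387 units, 12 units holding 26 genes were at least 4-fold higher in the xylose phase with at least 50 reads in the higher library, and 17 units holding 27 genes were at least 4-fold lower. Beyond the 3 xyl units, the units with the largest ratios included yicI-yicJ, which encodes an alpha-xylosidase and a putative transporter, at 62.7-fold higher (51.8 to 77.3). The unit yagG-yagH, of a putative transporter and a putative beta-xylosidase, was 52.1-fold higher (42.0 to 66.3). The propionate catabolism unit prpB-prpC-prpD-prpE was 35.2-fold higher (26.1 to 49.9), and tnaC-tnaA, with the tryptophanase gene, was 10.7-fold higher (8.23 to 14.4). The insertion sequence unit insE1-insF1 had 0 reads in the glucose phase and 156 in the xylose phase, at least 62.2-fold higher than 3 reads would give, but copies of this element share reads, so its value is uncertain, and a prior count of 5 gave a log2 ratio of 5.27. On the lower side, 3 of the largest ratios belonged to uptake of iron-binding siderophores. The unit fes-ybdZ, with the enterobactin esterase gene, was 10.1-fold lower, and the siderophore receptor genes fiu and cirA were 8.41-fold and 7.97-fold lower. The unit glnK-amtB, of a nitrogen regulatory protein and the ammonium transporter, was 7.08-fold lower (5.82 to 8.75), and nac, a regulator of nitrogen assimilation, was 6.78-fold lower (4.43 to 11.3). The aspartate oxidase gene nadB, of NAD synthesis, was 6.73-fold lower (5.65 to 8.13), and yedL was 7.06-fold lower (4.02 to 14.6). With deposited TPM plus 1, the log2 ratio of prpB-prpC-prpD-prpE was 4.02 in place of 5.14, and that of fes-ybdZ was -2.49 in place of -3.34.

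The medians of 21 of the 56 gene lists with measured units lay outside the range that holds 95% of random lists matched on expression, 9 above it and 12 below. For lists of units drawn at random 2.8 would. Members of a real list are not independent, so 2.8 is not a chance expectation for these lists. The percentile describes these libraries. The xylose list had a median log2 ratio of 8.79 over 3 units, and all 3 were at least 4-fold higher. The glycerol list had a median of 1.18 over 5 units, all above 0 and none past 4-fold, with glpA-glpB-glpC, of the anaerobic glycerol-3-phosphate dehydrogenase, 3.57-fold higher and glpQ-glpT 3.40-fold higher. In the list of flagella and chemotaxis, 14 of 15 units were above 0 and the median was 0.60, with flhE-flhA 2.08-fold and fliF-fliG-fliH-fliI-fliJ 1.85-fold higher, and no unit passed 4-fold. All 12 glycolysis units were above 0, with a median of 0.37 and ratios of 1.66 for pykF and 1.65 for pfkA. All 10 units of mixed acid fermentation and anaerobic respiration were above 0 as well, with a median of 0.37, and the largest ratio was that of adhE, encoding an alcohol dehydrogenase, at 3.73. The gene dcuC of that list was 2.22-fold higher from 19 and 10 reads (1.01 to 5.47).

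Smaller lists above their random range were the terminal oxidases, the glyoxylate bypass with acetate uptake, and the catabolism of galactitol, mannitol and sorbitol. The terminal oxidase list had a median log2 ratio of 0.90 over 3 units. Both units above 0 belong to the bd-I oxidase, cydA-cydB at 1.87-fold and its small subunit gene cydX at 2.03-fold higher, while cyoE-cyoD-cyoC-cyoB-cyoA, of the cytochrome bo oxidase, had a log2 ratio of -0.49. The glyoxylate and acetate list had a median of 0.53 over 3 units, with actP-yjcH-acs, which holds the acetyl-CoA synthetase gene, 2.70-fold higher (2.54 to 2.86) and glcB-glcG-glcF 1.45-fold higher. The list of galactitol, mannitol and sorbitol had a median of 0.43 over 3 units, with the gat unit 1.94-fold and mtlA-mtlD-mtlR 1.35-fold higher and srlA-srlE-srlB-srlD-gutM-srlR-gutQ at a log2 ratio of -0.31. Amino acid catabolism had a median of 0.25 over 10 units, of which 6 were above 0 and 1, tnaC-tnaA, was at least 4-fold higher. Within it, dadA-dadX, of alanine degradation, was 3.65-fold higher (3.35 to 3.99).

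Below their random ranges were lists of iron, nitrogen, sugar transport and biosynthesis. Of 13 iron acquisition units, 12 were below 0 and 4 at least 4-fold lower, and the median log2 ratio was -1.65. The nitrogen limitation list had a median of -2.76 over 3 units, 2 of them at least 4-fold lower. All 8 arginine units were below 0, with a median of -1.22 and none past 4-fold. Among them carA-carB, of carbamoyl phosphate synthesis, was 3.88-fold lower and argF was 2.72-fold lower, although argF shares sequence with argI and their split of reads is uncertain. The phosphotransferase list had a median of -1.05 over 3 units, all below 0, with ptsG 10.6-fold and manX-manY-manZ 2.07-fold lower. In the maltose list 7 of 8 units were below 0, with a median of -0.80, malQ-malP 4.32-fold lower (3.98 to 4.70) and malS 2.88-fold lower. The ribosomal protein list had a median of -0.38, with 19 of 21 units below 0 and none past 4-fold, and both rpsI-rplM and tff-rpsB-tsf were 1.45-fold lower.

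The remaining lists below their ranges were of nucleotide and amino acid synthesis. The pyrimidine list had a median log2 ratio of -0.76 over 5 units, with pyrD 3.27-fold and pyrC 1.78-fold lower. The unit eno-pyrG was 1.56-fold higher, but it also holds eno of the glycolysis list, and reads of its genes were counted together. The purine list had a median of -0.57 over 10 units, with guaA-guaB 2.06-fold and ubiX-purF-cvpA 1.70-fold lower, and 2 units were above 0, purA at 1.49-fold and purC at 1.12-fold higher. The list of glutamate, glutamine and asparagine synthesis had a median of -0.56 over 5 units, with glnL-glnA 2.13-fold and gltB-gltD-gltF 1.53-fold lower. In the aromatic list the median was -0.37 over 10 units, of which 8 were below 0, and tyrA-aroF, of tyrosine synthesis, was 4.98-fold lower (4.67 to 5.33) and aroH 1.84-fold lower. The histidine and tryptophan lists had 1 measured unit each, 2.15-fold lower for the his operon and 2.61-fold lower for trpA-trpB-trpC.

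**Figure D2:**
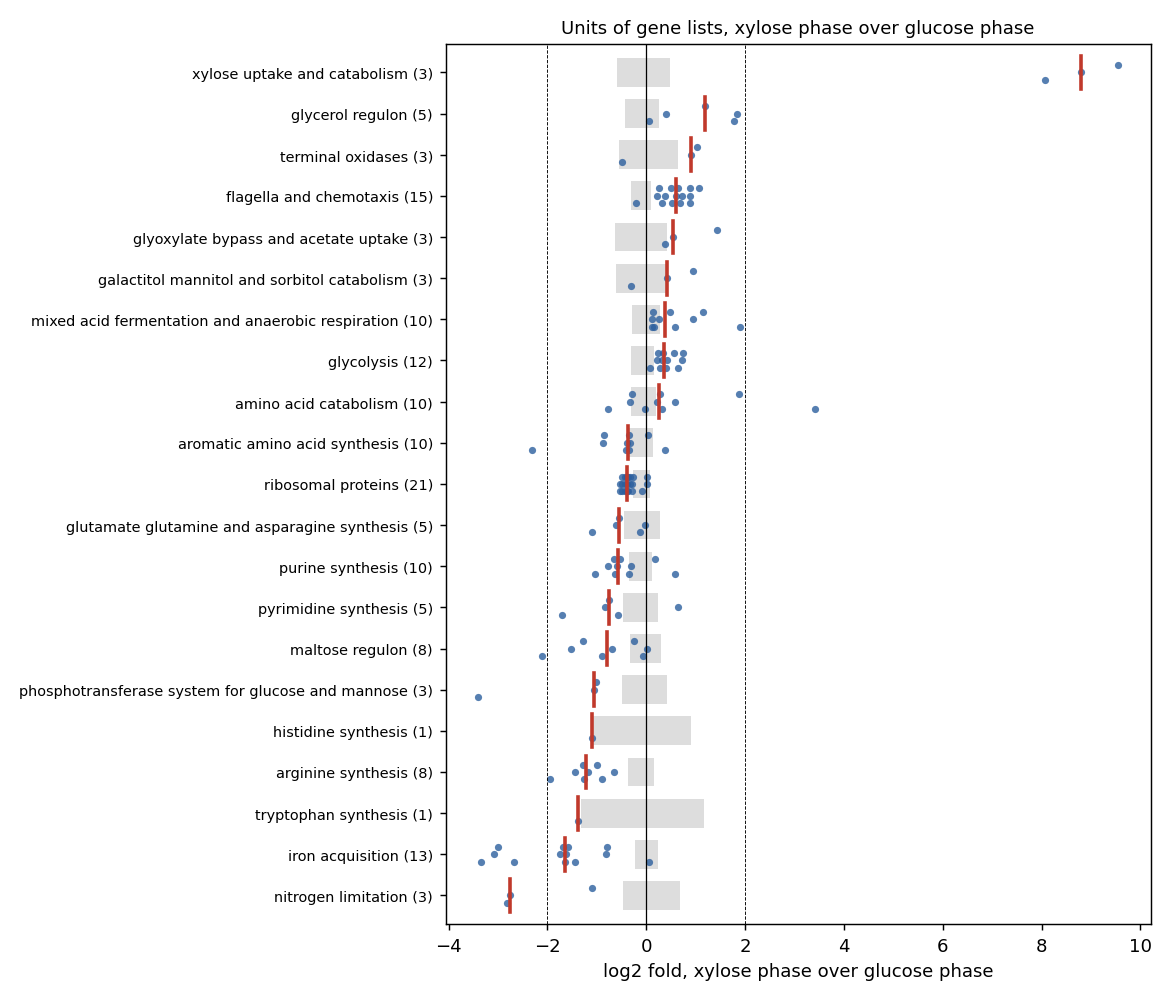
Log2 ratios of the xylose phase over the glucose phase (x axis) for the units (dots) of the 21 gene lists whose medians (red lines) lay outside their random ranges, with the number of units in parentheses, 1 library per phase. Grey bars hold the medians of 95% of 10000 random lists of the same size and expression, dashed lines mark a 4-fold difference, and the xylose list stands farthest out, at 8.79.

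Several genes named before the data were examined differed by less than 4-fold between the phases. The gene crp, encoding the cAMP receptor protein, stood at 0.999-fold (0.949 to 1.05), a difference not detectable at this depth. The lactose unit lacA-lacY-lacZ was 1.14-fold lower from 71 and 97 reads, and its interval (0.832 to 1.57) includes no difference. The flagellin gene fliC was 1.24-fold higher (1.23 to 1.25) and gapA, of glycolysis, was 1.32-fold higher (1.30 to 1.34). The maltose transporter unit malG-malF-malE was 1.86-fold lower (1.72 to 2.00), metE, of methionine synthesis, was 2.02-fold lower (2.00 to 2.04) and rpsA-ihfB was 1.41-fold lower. With at least 10 in place of 50 reads in the higher library, 21 units were at least 4-fold higher, and with at least 200 reads 11 units were at least 4-fold lower. The phases also differed in culture density, so carbon source and density cannot be told apart.

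The comparison of LB with the glucose phase asked how transcripts differed between a rich and a minimal medium. The medians of peptide and amino acid uptake and of 7 of the 10 lists of amino acid synthesis lay below their random ranges in LB. The median of the ribosomal protein list lay above its range. The gene metE, encoding the cobalamin-independent methionine synthase, was 674-fold lower in LB (634 to 718), with 1022 reads in LB and 119019 in the shallower glucose phase library. The gene ilvC, of valine and isoleucine synthesis, was 175-fold lower (165 to 185), and livJ, encoding a binding protein for branched-chain amino acids, was 131-fold lower (124 to 138). The ferric citrate transport unit fecE-fecD-fecC-fecB-fecA was 116-fold higher in LB (105 to 128), and cadA-cadB, of lysine decarboxylation, was 115-fold higher (77.1 to 190). Of 21 ribosomal protein units, 18 were above 0, with a median log2 ratio of 1.01 and none at least 4-fold higher. LB was prepared and sequenced by another provider with other kits and sampled at another culture density, so the medium cannot be told apart from library preparation or density.

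In LB, 100 units holding 133 genes were at least 4-fold higher than in the glucose phase and 205 units holding 317 genes were at least 4-fold lower. The minimum of 50 reads is a lower scaled level in LB, the deeper library, so these counts rest on unlike limits of level. On the higher side, the largest ratio among units with reads in both libraries was that of emrD, encoding a multidrug efflux pump, at 336-fold from 4862 and 2 reads (116 to 3469), ahead of the fec and cad units. The gene yceQ had 1456 reads in LB and 0 in the glucose phase, at least 83.9-fold higher. The genes yqgC at 81.7-fold (42.4 to 218), yqeG at 58.9-fold (35.8 to 115) and the prophage gene rzpD at 45.4-fold from 656 and 2 reads (15.6 to 469) followed. The insertion sequence gene insA4, whose copies share reads, had 175 and 0 reads, at least 10.1-fold higher. The 8 largest ratios on the lower side all belonged to units with 0 reads in LB. Compared with 3 reads in LB, rpmJ was at least 9976-fold lower, the leader peptide genes ilvL, ivbL, thrL and pyrL at least 687-fold, 633-fold, 214-fold and 203-fold lower, cydX at least 382-fold, yliM at least 174-fold and uof at least 162-fold lower. For units with 0 reads in 1 library the ratio depends on the prior count, so bounds are given, and a prior count of 5 gave log2 ratios of 5.66 for yceQ, 2.64 for insA4 and -12.55 for rpmJ. With that prior count the log2 ratio was 6.91 for emrD (8.39 with 0.5), 5.68 for yqgC (6.35) and 4.03 for rzpD (5.50). With deposited TPM plus 1 it was 6.08 for emrD, 7.18 for yqgC, 4.67 for rzpD, 5.41 for cadA-cadB (6.85) and 5.05 for yqeG (5.88). The 8 units on the lower side are 66 to 135 bases long. All 8 coding units shorter than 130 bases with at least 50 reads in the glucose phase had 0 reads in LB. The bounds of the 8 units on the lower side can therefore not be told apart from an effect of unit length.

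The medians of 24 of 56 gene lists lay outside their random ranges, 9 above and 15 below. In the list of peptide and amino acid uptake all 5 units were at least 4-fold lower in LB, with a median log2 ratio of -6.06. After livJ the next largest ratio was that of livK, at 68.3-fold lower, and livJ and livK are similar genes that can share reads. All 4 units of branched-chain amino acid synthesis were at least 4-fold lower (median -5.53), and leuD-leuC-leuB was 60.2-fold lower. All 8 arginine units were at least 4-fold lower (median -5.01), with argI 91.5-fold and argF 50.2-fold lower. In sulfate assimilation and cysteine synthesis 5 of 6 units were at least 4-fold lower (median -4.59), with cysC-cysN-cysD 118-fold and cysH-cysI-cysJ 91.5-fold lower. In methionine synthesis 5 of 8 units were at least 4-fold lower (median -2.65), and metF was 79.1-fold lower.

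The other lists of amino acid synthesis below their ranges had smaller medians. The list of glutamate, glutamine and asparagine had a median log2 ratio of -1.85 over 5 units, with the glutamate dehydrogenase gene gdhA 39.9-fold and the glutamate synthase unit gltB-gltD-gltF 17.4-fold lower. The aromatic list had a median of -1.47 over 10 units, 4 of them at least 4-fold lower, with serC-aroA 8.20-fold and aroG 7.70-fold lower. The list of threonine and lysine had a median of -1.30 over 8 units, 3 of them at least 4-fold lower, with lysC 17.0-fold and lysA 11.7-fold lower. The other 3 lists of amino acid synthesis lay inside their random ranges, tryptophan (-4.40) and histidine (-2.66) with 1 unit each, and serine, glycine and proline (median -1.41) with 2 of 6 units above 0. In purine synthesis 7 of 10 units were at least 4-fold lower (median -3.12), with purT 33.4-fold and purC 27.9-fold lower. The nitrogen limitation list had a median of -3.93 over 3 units, with glnK-amtB 17.7-fold and nac 15.2-fold lower, and with deposited TPM plus 1 both the median and nac were at -3.31.

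The lists of the tricarboxylic acid cycle, of glyoxylate and acetate, of RpoS, of flagella and chemotaxis and of fatty acid degradation were lower in LB as well. In the tricarboxylic acid cycle, for which 9 of 17 listed genes were measured, 4 of 8 units were at least 4-fold lower and 6 were below 0 (median -2.13), with the isocitrate dehydrogenase gene icd 8.45-fold and the malate dehydrogenase gene mdh 8.17-fold lower. The glyoxylate and acetate list had a median of -3.14 over 3 units, with aceB-aceA-aceK 23.4-fold and actP-yjcH-acs 8.83-fold lower. In the list of RpoS, the general stress sigma factor, 7 of 14 units were at least 4-fold lower and 13 were below 0 (median -2.49), with osmE 20.6-fold and elaB 18.1-fold lower. In flagella and chemotaxis 5 of 15 units were at least 4-fold lower (median -1.17), with fliC 16.1-fold and the chemotaxis unit cheZ-cheY-cheB-cheR-tap-tar 9.94-fold lower, while 5 units of the list were above 0. Fatty acid degradation had a median of -1.49 over 6 units, with fadE 6.25-fold and fadA-fadB 5.55-fold lower and fadL, encoding the outer membrane transporter of long-chain fatty acids, 4.11-fold higher.

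**Figure D3:**
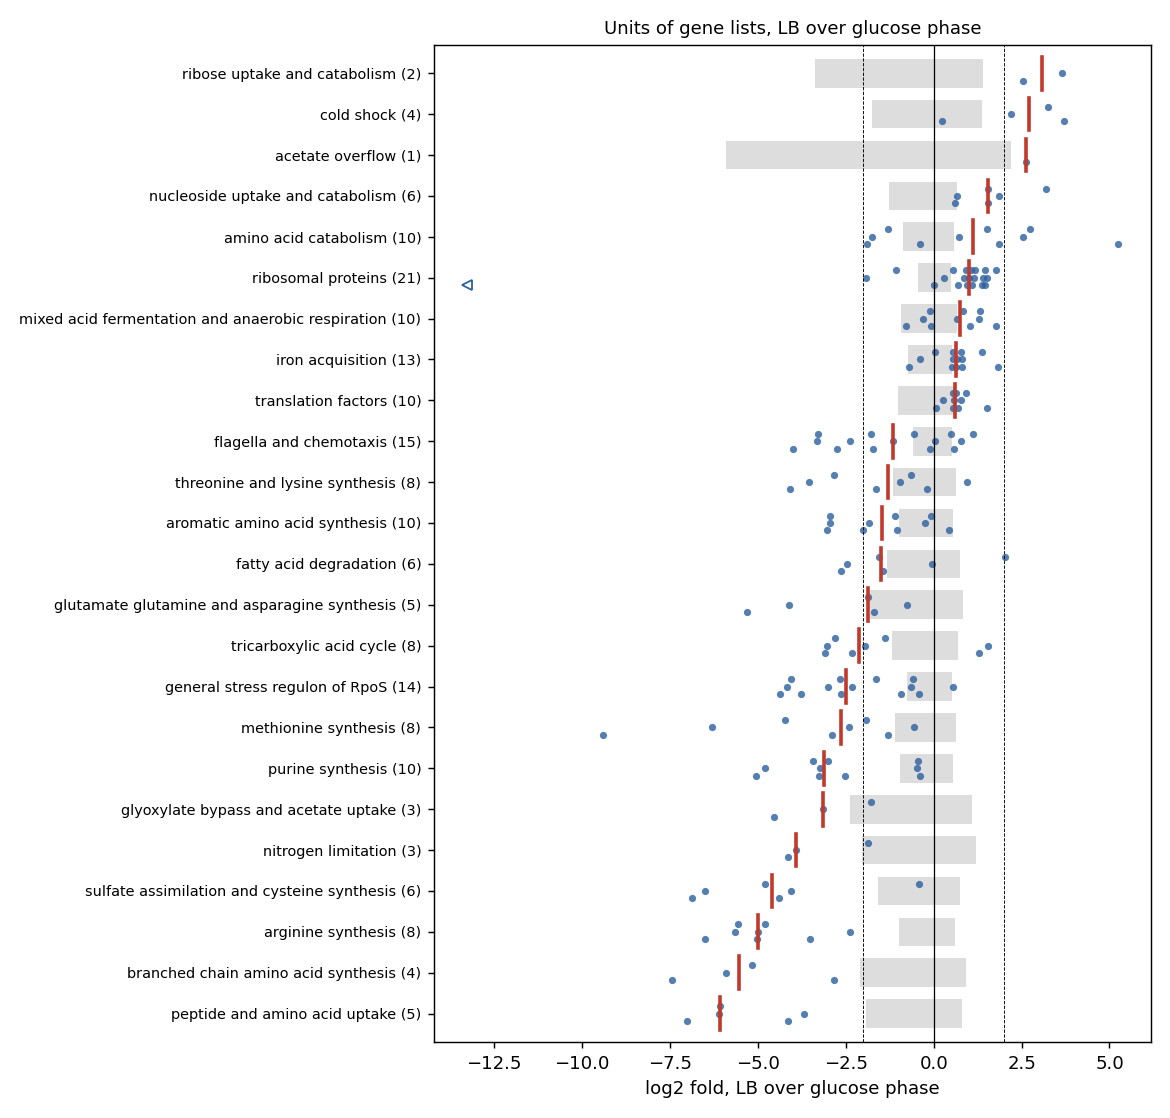
Log2 ratios of LB over the glucose phase (x axis) for the units (dots) of the 24 gene lists whose medians (red lines) lay outside their random ranges, with the number of units in parentheses, 1 library per medium. Grey bars hold the medians of 95% of 10000 random lists of the same size and expression, dashed lines mark a 4-fold difference, and the open triangle marks rpmJ, with 0 reads in LB, at the bound that 3 reads would give, while peptide and amino acid uptake has the lowest median, at -6.06.

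Among the lists higher in LB was ribose use, whose 2 units were both at least 4-fold higher, rbsD by 12.5-fold and rbsC-rbsB-rbsK by 5.82-fold. The acetate overflow list had 1 measured unit, ackA-pta, at 6.21-fold higher (6.05 to 6.38). In the cold shock list, for which 4 of 6 genes were measured, 3 of 4 units were at least 4-fold higher (median log2 ratio 2.72), with cspA 13.0-fold (11.5 to 14.8) and cspG 9.55-fold higher, the latter from 193 and 3 reads (3.75 to 54.4). Both genes are 213 bases long, and division of counts by each library's effective length moved cspA from a log2 ratio of 3.70 to 4.54, cspG from 3.26 to 4.30 and the median to 3.69, while a prior count of 5 gave 2.10 for cspG. All 6 units of nucleoside uptake and catabolism were above 0 (median 1.55), with the cytidine deaminase gene cdd 9.08-fold and the deo operon 3.60-fold higher. Amino acid catabolism had 3 of 10 units at least 4-fold higher and 4 below 0 (median 1.11), with sdaC-sdaB, of serine uptake and deamination, 37.8-fold (35.7 to 40.1) and tdh-kbl, of threonine degradation, 6.66-fold higher. Among ribosomal protein units rpmA-rplU was 3.42-fold and rplT-rpmI-infC 2.84-fold higher, and 3 of the 21 units were below 0. Of these only rpmJ was counted as at least 4-fold lower, and its 0 reads in LB may reflect its length of 117 bases. All 10 translation factor units were above 0 (median 0.61), with serW-infA 1.90-fold higher.

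Iron acquisition had 11 of 13 units above 0 and none past 4-fold (median log2 ratio 0.64), with the receptor gene fiu 3.56-fold and fhuA-fhuC-fhuD-fhuB, of ferrichrome uptake, 2.58-fold higher. That list does not hold the fec unit. Mixed acid fermentation and anaerobic respiration had 6 of 10 units above 0 (median 0.75), with frdD-frdC-frdB-frdA, of fumarate reductase, 2.51-fold higher and dcuC 3.43-fold higher from 208 and 10 reads (1.92 to 7.61). With deposited TPM plus 1 in place of scaled counts that median moved to 0.58, inside its random range, and the log2 ratio of dcuC from 1.78 to 1.08. Among the genes named beforehand, the lac unit was 5.06-fold higher in LB (4.15 to 6.29), rpsA-ihfB was 1.82-fold higher (1.81 to 1.84) and gapA was 1.32-fold higher (1.31 to 1.33). The unit malG-malF-malE was 3.53-fold lower (3.35 to 3.72), ptsG was 1.67-fold lower (1.64 to 1.71) and crp was 1.17-fold lower (1.13 to 1.22). The unit xylF-xylG-xylH-xylR was higher by a log2 ratio of 0.59 (a ratio of 1.30 to 1.76), and xylB-xylA was 1.13-fold lower with an interval (0.962 to 1.33) that includes no difference.

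LB was also set against the xylose phase. The genes of xylose use were lower in LB, with a median log2 ratio of -8.53 over 3 units, all 3 at least 4-fold lower. Iron acquisition units were higher in LB, 9 of 13 by at least 4-fold, with a median of 2.33. The units with the largest ratios on the higher side were cadA-cadB at 197-fold (112 to 431), the fec unit at 164-fold (145 to 187) and emrD at 108-fold (53.7 to 319). With deposited TPM plus 1 the log2 ratio of cadA-cadB was 5.64 in place of 7.62 and that of emrD 5.53 in place of 6.76. On the lower side rpmJ, ilvL and ivbL had 0 reads in LB and were at least 7692-fold, 955-fold and 932-fold lower. They are 117, 99 and 99 bases long. All 8 coding units under 130 bases with at least 50 reads in the glucose phase had 0 reads in LB. These bounds can therefore not be told apart from an effect of unit length. Over all units 118 were at least 4-fold higher and 222 at least 4-fold lower, again with unlike limits of level. The medians of 19 lists lay outside their random ranges, 7 above and 12 below. The list of peptide and amino acid uptake had a median of -5.72, branched-chain amino acid synthesis -5.59, sulfate assimilation -4.88 and arginine synthesis -3.67, while ribosomal proteins had a median of 1.39. This comparison shares the LB library with the comparison against the glucose phase, and also differs in library provider, kits and culture density.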

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

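The tests of units shorter than 150 bases and of the other ribosomal protein units were chosen only after the results were seen. For the remaining tests, what each would show was written before its value was computed, but after the pattern had been noticed in the same data.

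The LB library holds 8811 reads of ERCC spike-in sequences, synthetic RNAs added as standards, although the labels name no spike-in and no control library exists. These are 0.0242% of its assigned reads (95% interval 0.0237 to 0.0248), spread over 46 of 92 listed sequences, with 2365 reads on ERCC-00130 and 1892 on ERCC-00096.

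The small RNA gcvB, which lies outside the counts of protein-coding units, has 50926 reads in LB, far above the limit that a count of 0 allows, against 15 in the glucose phase and 26 in the xylose phase, a log2 ratio of 9.15 over the glucose phase (26368 against 22.5 TPM). GcvB is known to repress many messages for amino acid uptake and synthesis. From a list of 20 targets, written from general knowledge before the test and not checked against the literature, 10 units were in none of the gene lists of the report. Their median log2 ratio in LB was -0.88, at percentile 2.76 of matched random lists and inside the range that holds 95% of them (-0.91 to 0.55), with 8 of 10 below 0 and 2 at least 4-fold lower, hisP-hisM-hisQ-hisJ-argT (9.84-fold) and metQ-metI (4.70-fold). The test therefore does not decide whether lower target RNA accompanies GcvB in LB, and other regulators of amino acid transport and the change of provider, kits and culture density stay open as well.

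In LB, 9 protein-coding units with at least 50 reads in the glucose phase have 0 reads and were counted as lower. The other ribosomal protein units had a median log2 ratio of 1.03, with 18 of 20 above 0, so rpmJ stood apart from its list. That median was in effect known from the list with rpmJ. It therefore does not decide whether transcription of rpmJ was lower. Loss of short features from the library or its quantification is a candidate explanation, as 9 of 12 coding units under 150 bases (75%) and 0 of 1781 longer ones were at 0, although 75% fell short of the 80% set for that length. At a limit of 130 bases, taken after seeing the coding units, 8 of 8 coding units were at 0, and in a separate set of features without a protein-coding gene 8 of 8 were (100%), namely 7 transfer RNAs and sdhX. In LB the deposited effective length equalled the full length for alaT (76 bases), sdhX (101) and fnrS (122), all with 0 reads. In the glucose phase it was 1.15, 10.5 and 19.5 bases. A count of 0 in LB for features this short therefore does not show that their RNA was low. Whether fragments were lost in preparation or in read assignment stays open. So does lower transcription of rpmJ and of the leader peptides ilvL, ivbL, thrL and pyrL in a rich medium.

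The 10 lists of amino acid synthesis had a median of list medians of -2.65 in LB over the glucose phase. A trend with unit length between the kits is argued against as the whole cause, since the value was -2.82 after the median ratio of units of like length was subtracted. Thinning LB to the smallest library gave -2.63, which decides nothing about depth, since thinning leaves the expected ratio of well-counted units as it was. Amino acids supplied by LB may lower these transcripts, which remains a hypothesis, because medium, culture density, provider, depletion kit, library kit and instrument changed together and cannot be told apart.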

How the results depend on the processing

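The alternatives by unit length, insertion sequences and units inside other units were chosen after seeing the data. For units chosen by the naming rule and for list medians, 9 alternatives were computed, those fixed beforehand other than the read minimums. Under these no such unit and no list median outside its random range changed sign, except crp between the phases, at a log2 ratio of -0.00, which was 0.03 with total counts of all features and 0.12 with deposited TPM plus 1. Of the list medians under these alternatives, 1501 stayed on their side of the random range, 7 moved outside it and 4 moved inside. Those 4 were mixed acid fermentation for LB over the glucose phase with TPM plus 1 (0.58), and acetate overflow for LB over the xylose phase, a list of 1 unit, with TPM plus 1, TPM plus 0.1 and effective length. Of the values of the units chosen by the naming rule, 962 stayed within their counting interval and 226 moved beyond it. Units named only in the closing parts, or for going against their lists, were not recomputed. Counts of units at least 4-fold apart stayed within 1.5 times their value under every alternative, except between the phases, where 21 units were higher with a minimum of 10 reads and 11 lower with 200 reads, since these limits admit more or fewer units. Units shorter than 300 bases made up part of the units lower in LB than in the glucose phase, 170 of 205 remaining without them. With log2(TPM + 0.1), Pearson r was 0.958 between the phases, 0.796 for LB and the glucose phase and 0.771 for LB and the xylose phase, and among units with TPM of at least 10 in both libraries it was 0.769 and 0.759 for the pairs with LB. The cause of these shifts in r was not tested. Deposited TPM plus 0.1 moved the median of all units by 0.11 (log2) between the phases, and a prior count of 5 by -0.12 for LB over the xylose phase. With 1 library per group no library can be left out. No paired analysis was possible because each group has 1 library. At the depth of the diauxic libraries, units under 50 reads in both were not counted whatever their ratio.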

Other observations

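The units in this part were chosen after their values were seen, and the test of units inside other units was written before its value was computed. The units thiE and thiH-thiG-thiS were 50.1-fold and 40.7-fold lower in LB than in the glucose phase, with thiD-thiM at a log2 ratio of -2.69 and thiI at 1.06. The genes rmf, encoding the ribosome modulation factor that forms inactive ribosome dimers, and sra, encoding a stationary phase ribosome-associated protein, were 70.4-fold and 47.4-fold lower in LB, from 43 reads of rmf and 13 reads of sra there, and sra is 138 bases long, near the length at which units had no reads in LB. In deposited TPM the ratios were smaller, with 70.2 for rmf in LB and 1188 in the glucose phase, and 55.2 and 388 for sra. The pyruvate transporter gene btsT was 41.3-fold, the peptide transporter gene dtpA 20.3-fold and the formate dehydrogenase unit fdhE-fdoI-fdoH-fdoG 17.9-fold higher in LB. The cytosine unit codB-codA was 18.8-fold lower in LB.

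Between the phases, the units codB-codA and uraA-upp, the latter of uracil uptake and use, were lower in the xylose phase, with log2 ratios of -2.18 and -2.13. The genes grcA, encoding a stress-induced glycyl radical protein, and hokB-mokB, of a toxin system, were 4.45-fold and 4.89-fold higher in the xylose phase. The galactose symporter gene galP was lower, from 590 to 95 reads. The gene rmf was 3.39-fold higher in the xylose phase.

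The outer membrane porin gene ompC was 5.22-fold higher and the porin gene ompF 7.85-fold lower in LB than in the glucose phase. Among RNAs without a protein-coding gene, the regulatory RNA csrC was 10.7-fold and the RNA polymerase-binding RNA ssrS 7.49-fold lower in LB, whereas the transfer RNA units lysT-valT-lysW and valU-valX-valY-lysV were 6.55-fold and 6.94-fold higher. In deposited TPM the ratios of csrC and ssrS were smaller, with 374 for csrC in LB and 2660 in the glucose phase, and 3511 and 9526 for ssrS. Between the phases csrB was 2.45-fold higher in the xylose phase.

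A check for reads of overlapping units in LB decided nothing, since only 2 tested units lie at least 50% inside another unit, with a median log2 ratio of 0.20.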
